A study of Arabidopsis thaliana and Marchantia polymorpha with 6 samples.

How the data were processed

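DNA affinity purification sequencing (DAP-seq) reads out which fragments of naked genomic DNA a recombinant protein holds in a test tube. Per the labels' protocols, each protein was made in Escherichia coli, bound to amylose beads and offered genomic DNA broken to a mean of 200 bp with sequencing adapters attached. The DNA came from 10-day-old Col-0 seedlings of Arabidopsis thaliana and from 21-day-old Tak-1 gemmalings of the liverwort Marchantia polymorpha. The labels describe 6 samples in 6 groups: AtPIF4, AtHY5 and an input for Arabidopsis, and MpPIF, MpHY5 and an input for Marchantia. Each has 1 library, so no value has a replicate error. Every test compares event lists or genes of single libraries, not replicated conditions.

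Event lists were used for AtPIF4, for AtHY5 and for a Marchantia HY5 list that belongs to the series as a whole and is called the MpHY5 list here. MpPIF and both inputs were not analysed here. Reads were trimmed with Trim Galore and aligned with Bowtie2, per the submitters' processing notes, which give no versions. Events were called with GEM, per the file headers. GEM places each binding event at a single position. The build TAIR10 is named for all samples per the submitters' processing notes. The chromosome names of the Marchantia list are not those of Arabidopsis, so its build is not given in the sources used here. All 3 deposited lists give each event as an interval of 200 bp with its centre in the middle, and a score that the authors' caller assigned. What the score measures and how it was normalized is not stated. It was therefore used to describe and rank events within a list, and score values were not compared between lists. The rule for named genes adds ranks taken within each list. Read counts were not used here, so the depth of each library is unknown, and a longer list can come from a deeper library.

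Positions are 1-based. Genes came from a table of the assembly TAIR10.1, whose name differs from the TAIR10 of the lists, so none of its coordinates are printed. As a check of the match, events were shifted by 1000 and 2000 bp in each direction. The share of events inside genes was highest without a shift, at 63.1% for AtPIF4 and 65.3% for AtHY5, against 55.3% to 57.9% after a shift. The same held in the outer parts of the chromosomes. The table held 27444 protein-coding genes on 5 nuclear chromosomes and gave no strand, exons or untranslated regions. An upstream region of 1000 bp had been planned. Without strand, a gene was instead said to have a flanking event when an event centre lay within 1000 bp beyond either gene end. That replacement was made before any gene result was computed. A flank can include part of a neighbouring gene, and 1 event can serve 2 genes, so genes are not independent. Events were divided into those inside a protein-coding gene, those within 1000 bp of one, and those farther away. Exon, intron and untranslated region classes were not run. No genome sequence was used here. The planned motif shares, their comparison between AtPIF4, AtHY5 and MpHY5, and the 6-mer correlation were not run. Marchantia genes were not analysed here.

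Events of AtPIF4 and AtHY5 were called near each other when their centres lay within 100 bp. The number near was set against 1000 random placements of the events on the same chromosome, with a one-sided permutation p. The same numbers were computed for distances of 50 and 200 bp, for events above the median score, for the 1000 highest scores, and for placements that keep each event's class. Genes with events of both proteins were tested with Fisher's exact test, two-sided, over all protein-coding genes. Its odds ratio is given, because its p was too small for the computer's number format in the comparison reported. Shares have 95% Wilson intervals, and densities have 95% Poisson intervals. These cover counting error only.

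Before the data were examined, 12 gene lists with 250 members were fixed from general knowledge of light and temperature biology: light signalling, B-box proteins, flavonoid and anthocyanin, chlorophyll synthesis, light harvesting and photosynthesis, carotenoid, circadian clock, auxin, shade and elongation, gibberellin and brassinosteroid, heat and cold, and a housekeeping comparison list. All 250 members were found by identifier. The members of each list with a flanking event were counted and set against 10000 random lists of the same size, matched on 5 classes of the summed gap to both neighbouring genes. For the window that adds the gene body, random lists were matched on 5 classes of gene length as well. The permutation p is one-sided, and Benjamini-Hochberg adjustment ran over all 24 tests. The planned windows were 500 bp, 2000 bp, and 1000 bp beyond to 500 bp inside either gene end. Events above the median score and a one-sided Fisher's exact test without matching, against all protein-coding genes, were also planned. A further 3 alternatives were chosen after seeing the data. They were the gene body with 1000 bp beyond either end, as many AtHY5 events as AtPIF4 events, and lists without repeated blocks. The last left out events within 10 kb of an rRNA gene or of the highest-scoring 1% of either list.

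Named genes follow a rule fixed before the data were examined. It takes HY5 and PIF4, up to 3 members per list with the highest-scoring flanking event of each protein, the 10 genes with the highest-scoring flanking event of each protein, and the 10 with the lowest sum of ranks in both. The placement and list tests were tested on simulated data. Of 500 pairs planted between AtPIF4 and AtHY5 lists, 497 were recovered as excess. None of 20 unrelated placed lists gave p under 0.05. Both checks used uniformly placed lists, as in the random placements. They test the computation and do not show that uniform placement suits the real lists. Among 200 simulated AtHY5 lists of 24 genes per size, drawn over 27444 genes, 3% of null lists gave p under 0.05. The share was 30% for lists planted at 1.5 times the random rate and 94.5% at 2.4 times. These p were not adjusted, and list calls used adjusted p, so the shares are upper bounds for such calls. AtPIF4 and lists of other sizes were not simulated. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.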

Results

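HY5 is a bZIP transcription factor that promotes seedling development in light, and PIF4 is a bHLH factor that promotes elongation growth in shade and warmth. The series measured by DAP-seq where these proteins of Arabidopsis, and their counterparts in the liverwort Marchantia, hold genomic DNA. Its title places the question in the origin of sensory integration before plants settled on land. The AtPIF4 list held 6699 events with a median score of 146, the AtHY5 list 16825 events with a median score of 117, and the MpHY5 list 32067 events with a median score of 84.8. Each list comes from 1 library of unknown depth, so the numbers of events are not compared as binding.

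AtHY5 events lay at 141 per Mb of the Arabidopsis nuclear chromosomes and AtPIF4 events at 56.2 per Mb. In both lists chromosome 3 had the lowest density, with 97.9 AtHY5 and 40.5 AtPIF4 events per Mb. For AtPIF4 its Poisson interval (37.9 to 43.1) overlapped that of chromosome 2 (41.3 to 47.2). Chromosomes 1 and 5 were the densest, at 165 and 158 AtHY5 events per Mb and at 65.7 and 66.1 AtPIF4 events per Mb. The Poisson intervals of these chromosomes overlapped in each list. MpHY5 events lay at 142 to 155 per Mb on the 8 Marchantia autosomes, with a mean of 151. The V chromosome, the male sex chromosome of the Tak-1 strain, held 377 events, or 50.3 per Mb (95% Poisson interval 45.4 to 55.7). The autosomal density was 3.0 times that of V (2.72 to 3.33 at the Poisson bounds of V). These bounds hold the autosomal mean fixed and leave out the spread among autosomes. Marchantia lengths were taken up to the last event of each chromosome. Events had a neighbour of the same list within 1000 bp more often than placed ones, at 36.8% against 26.0% for MpHY5, 18.5% against 11% for AtPIF4 and 38.0% against 25.3% for AtHY5. Each of these shares lay above the highest of 100 placements. The placements were uniform, but counts per bin of 1 Mb ran from 13 to 100 for AtPIF4 and from 19 to 239 for AtHY5. Local clustering was therefore not separated from regional density.

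**Figure D1:**
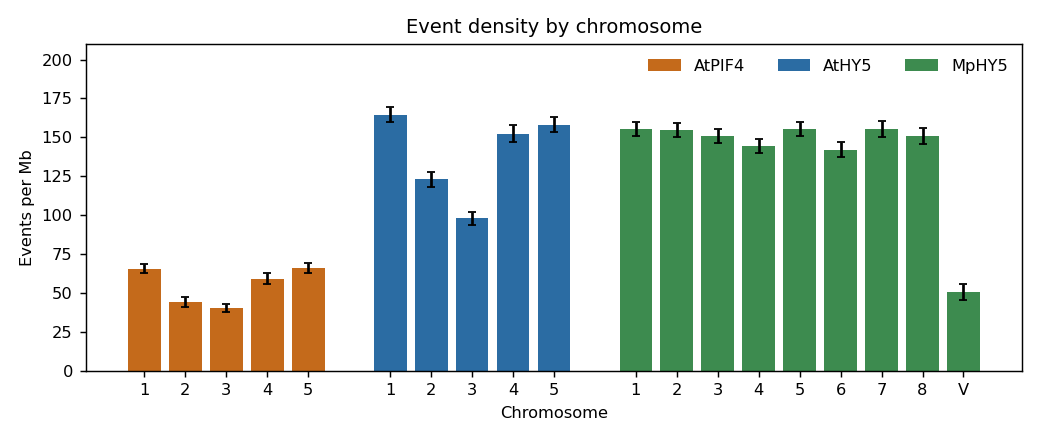
Events per Mb on each chromosome, with 95% Poisson intervals as error bars, for the AtPIF4, AtHY5 and MpHY5 lists of 1 library each. The Marchantia V chromosome stands at 50.3 per Mb, below the 8 autosomes at 142 to 155 per Mb.

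The first comparison asked whether AtPIF4 and AtHY5 take the same positions. Of the 6699 AtPIF4 events, 3170 had an AtHY5 event within 100 bp, or 47.3% (Wilson interval 46.1 to 48.5). Random placements gave a mean of 2.86% and a maximum of 3.52%, so the observed share was 16.5 times the mean. From the other side, 3323 of 16825 AtHY5 events, or 19.8% (19.2 to 20.4), had an AtPIF4 event within 100 bp, against 1.16% in placements. For both, the permutation p of 0.001 was the smallest that 1000 placements can give. The share rose with score within each list. It went from 35.7% in the lowest of 5 equal score classes of AtPIF4 events to 64.6% in the highest, and from 10.3% to 39.6% for AtHY5. Inputs were not analysed here, so positions that come up without a bound protein were not removed beyond what the authors' calling did.

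The centres of near events were often almost at the same base. Of 3355 pairs within 100 bp, 54.2% lay within 20 bp (52.6 to 55.9), and 1282 were 1 or 2 bp apart. Only 11 pairs had the same centre, while 845 were 1 bp apart, 437 were 2 bp apart and 26 were 3 bp apart. PRR9, a clock repressor, is an example on chromosome 2. Its flanking AtPIF4 event at 19232336 to 19232535 has a score of 376, and the AtHY5 event at 19232337 to 19232536 has a score of 237. DFR, an enzyme of anthocyanin synthesis, has such a pair on chromosome 5, at 17165945 to 17166144 for AtPIF4 and 17165944 to 17166143 for AtHY5. Such pairs also flank PHYA, a far-red photoreceptor gene, BBX19, a B-box protein gene, and COR15A, a cold-induced gene. Coordinates are those of the lists, whose build is named as TAIR10.

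**Figure D2:**
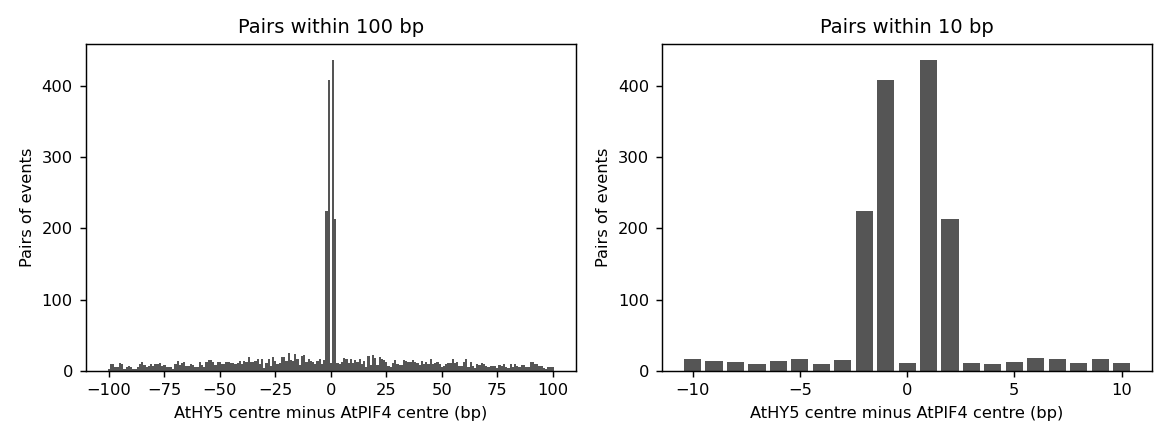
Number of AtPIF4 and AtHY5 event pairs by the AtHY5 centre minus the AtPIF4 centre in bp, for pairs within 100 bp and, in closer view, within 10 bp. Bars 1 and 2 bp to either side of 0 hold 1282 of the 3355 pairs, and 11 pairs stand at 0.

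Most events lay inside protein-coding genes. The share was 63.1% for AtPIF4 (61.9 to 64.2) and 65.3% for AtHY5 (64.6 to 66.1), against 54.5% and 54.4% in placements, whose highest values were 56.5% and 55.6%. Farther than 1000 bp from any gene lay 17.0% of AtPIF4 and 15.3% of AtHY5 events, below 25.1% in placements for both. Placements were uniform along each chromosome and did not follow regional event density. The flanks within 1000 bp held 19.9% of AtPIF4 and 19.4% of AtHY5 events. Both shares lay within the range of the placements, from 19.1% to 22.1% and from 19.0% to 21.4%. With the first 500 bp inside genes added, the shares were 48.7% and 51.4% and lay above the placements. By distance from the nearest gene end, the greatest excess stood 200 to 500 bp inside genes, at 1.60 times the placed share for AtPIF4 and 1.80 times for AtHY5. More than 1000 bp inside genes, both lists lay below the placed share. There the values were 13.4% against 17.4% for AtPIF4 and 11.8% against 17.3% for AtHY5. The gene table used gives no strand or exons, so gene starts, gene ends, introns and untranslated regions were not separated.

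**Figure D3:**
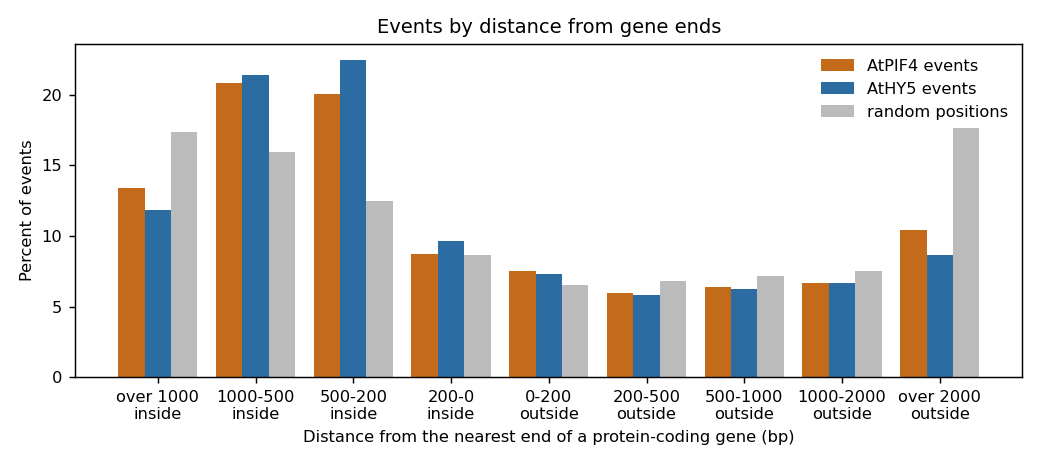
Percent of AtPIF4 events, AtHY5 events and randomly placed positions by distance in bp from the nearest end of a protein-coding gene, inside or outside it. Both lists exceed the placed share most at 200 to 500 bp inside genes, by 1.60 and 1.80 times.

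Many genes had flanking events of both proteins. Of 27444 protein-coding genes, 3126 had an AtPIF4 event and 7109 an AtHY5 event, and 1935 had both, which is 2.39 times the 810 that independent lists would share. The odds ratio was 6.01 (95% interval 5.56 to 6.50). The number of such genes moved with the window, from 932 within 500 bp to 4198 within 2000 bp, with odds ratios of 10.3 and 4.36. It was 4665 with the gene body added, a window chosen after seeing the data. By the sum of ranks, the leading genes outside rRNA blocks included AT2G07776, in a part of chromosome 2 known to hold inserted mitochondrial DNA, SHOT1, a gene with a role in heat tolerance, AT4G11730, AT2G24780 and LYK4, a LysM receptor-like kinase gene that acts in chitin responses. SHOT1 was flanked on chromosome 3 by an AtPIF4 event of score 2503 at 22327984 to 22328183 and an AtHY5 event of score 1361 centred 2 bp away. LYK4 was flanked on chromosome 2 by an AtPIF4 event of score 1177 at 10119576 to 10119775 and an AtHY5 event of score 1351 centred 1 bp away.

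The genes of the 2 proteins themselves had no flanking event within 1000 bp. Within 2000 bp of HY5, on chromosome 5, lay an AtHY5 event of score 900, higher than 98.2% of its list, and an AtPIF4 event of score 112, higher than 22% of its list. PIF4, on chromosome 2, had an AtHY5 event of score 90 inside the gene and another of score 240 within 2000 bp, and no AtPIF4 event in that range.

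The next comparison asked which groups of light and temperature genes carry flanking events. Of 24 list tests, 2 passed an adjusted p of 0.05, the circadian clock list for AtHY5 and the B-box list for AtPIF4. Both calls depend on the window. Neither held with 1000 bp beyond to 500 bp inside gene ends, where the adjusted p was 0.0773 for each, or with gene body and 1000 bp, where it was 0.186 for each. No list passed for either protein in those 2 windows, the second of which also matched random lists on gene length. Neither call held at 2000 bp, and the B-box call did not hold at 500 bp. Before adjustment, 5 lists for AtPIF4 and 4 for AtHY5 had p under 0.05. Of the 12 lists, 10 for AtPIF4 and 9 for AtHY5 lay above the random mean.

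Of the 24 circadian clock genes, 16 had a flanking AtHY5 event, against a mean of 6.60 in random lists (permutation p = 0.0001, the smallest that 10000 lists can give, adjusted permutation p = 0.0024). RVE8, which encodes a MYB-like activator of evening genes, had the highest score at 824, from an event at 2945209 to 2945408 on chromosome 3. PRR3 followed with 730 and BOA, a relative of the evening gene LUX, with 567. AtPIF4 events flanked 7 clock genes against 2.91 in random lists (permutation p = 0.0185, adjusted permutation p = 0.0888), among them RVE8 with a score of 474, PRR9 with 376 and ELF3, an evening complex gene, with 202. Whether the proteins differ over this list was not tested. Within 2000 bp, 17 clock genes had an AtHY5 event and the adjusted p was 0.0605.

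Of the 13 B-box genes, which encode zinc finger regulators of light responses, 6 had a flanking AtPIF4 event against 1.47 in random lists (permutation p = 0.0023, adjusted permutation p = 0.0276). BBX19 had a score of 482 at 18163813 to 18164012 on chromosome 4, BBX18 had 308 and BBX28 had 165. AtHY5 events flanked 6 B-box genes as well, against 3.32 in random lists (adjusted permutation p = 0.167). BBX28 had the highest AtHY5 score at 503, then BBX29 with 308 and BBX24 with 148. Within 500 bp, 1 of the 13 genes had an AtPIF4 event, and within 2000 bp 7 had one, with adjusted p of 0.823 and 0.0594.

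None of the pigment and photosynthesis lists passed the adjusted threshold. Among AtHY5 events above the median score, the light harvesting and photosynthesis list had 4 genes against 3.26, the flavonoid and anthocyanin list 5 against 3.32, the carotenoid list 2 against a mean of 2, and the chlorophyll synthesis list 6 against 3.65. In the light harvesting and photosynthesis list, 12 of 24 genes had an AtHY5 event against 5.98 (adjusted permutation p = 0.0504), and 6 had an AtPIF4 event against 2.66 (adjusted permutation p = 0.133). Among AtPIF4 events above the median score the direction turned, with 1 gene against 1.36. LHCB2.3, an antenna protein gene, had an AtHY5 score of 666. LHCB1.4 and LHCB1.5 are neighbours that share an event of score 519, so these members are not independent. LHCA2 with 195 and LHCB6 with 129 had the highest AtPIF4 scores of the list. In the flavonoid and anthocyanin list, 12 of 25 genes had an AtHY5 event against 6.13 (adjusted permutation p = 0.066) and 5 had an AtPIF4 event against 2.68 (adjusted permutation p = 0.223). At 2000 bp the AtPIF4 count turned below the mean, with 5 against 5.14. UGT78D2, a flavonoid glucosyltransferase gene, had an AtHY5 score of 271, and the flavonol regulators MYB111 and MYB12 had 235 each. DFR had the highest AtPIF4 score of this list, 458, followed by UF3GT with 247. Of 13 carotenoid genes, 7 had an AtHY5 event against 3.62 and 3 an AtPIF4 event against 1.61 (adjusted permutation p = 0.133 and 0.353). ABA1, which encodes zeaxanthin epoxidase, had an AtPIF4 score of 480, and BETA-OHASE1, a carotene hydroxylase gene, an AtHY5 score of 310. Chlorophyll synthesis genes stood near the random mean, with 8 of 24 for AtHY5 against 6.69 and 2 for AtPIF4 against 2.97 (adjusted permutation p = 0.493 and 0.815). For AtHY5 they turned below that mean at 2000 bp, with 10 genes against 11.1, and with the gene body, with 12 against 12.1. For AtPIF4 they turned above it at 2000 bp with 7 against 5.36, above the median score with 2 against 1.55, and with the gene body with 6 against 5.57. HEME2 had an AtHY5 score of 578, and the chlorophyll synthase gene G4 an AtPIF4 score of 271.

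Among 25 light signalling genes, 6 had an AtPIF4 event against 2.78 and 7 an AtHY5 event against 6.45 (adjusted permutation p = 0.133 and 0.613). The AtHY5 direction turned below the mean at 500 bp, with 500 bp inside and with the gene body. AtPIF4 events flanked FHL with a score of 464, PHYB, the main red light receptor gene, with 299, and PHYA with 254. AtHY5 events flanked RUP1, a repressor of ultraviolet-B signalling, with 290, PIF5 with 278 and FHY1 with 247. Of 21 shade and elongation genes, 5 had an AtPIF4 event against 2.0 and 8 an AtHY5 event against 4.52 (adjusted permutation p = 0.133 and 0.155). PIL2 had an AtPIF4 score of 901, PAR1, a gene for a repressor of shade responses, had 561, and CKX5, a cytokinin oxidase gene, had 524. CKX5 also had the highest AtHY5 score of the list at 564. Within 500 bp, 0 of the 21 genes had an AtPIF4 event against 1.01 in random lists, and 5 had an AtHY5 event against 2.43. Within 2000 bp the list passed for both proteins, with 14 genes for AtPIF4 (adjusted permutation p = 0.0024) and 15 for AtHY5 (adjusted permutation p = 0.0336).

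Of 24 auxin genes, 5 had an AtPIF4 event against 2.31 and 4 an AtHY5 event against 5.20 (adjusted permutation p = 0.155 and 0.815). Among events above the median score the auxin list passed for AtPIF4, with 5 genes against 1.13 (adjusted permutation p = 0.0384). For AtHY5 it turned above the mean at 2000 bp with 10 against 9.51, above the median score with 3 against 2.80, and with equal numbers of events with 3 against 2.3. YUC8, an auxin synthesis gene, had an AtPIF4 score of 262, and GH3.3, an auxin conjugation gene, had 226. IAA5, a repressor of auxin responses, had an AtHY5 score of 682. The gibberellin and brassinosteroid list had 2 of 22 genes with an AtPIF4 event against 2.09 and 6 with an AtHY5 event against 4.77 (adjusted permutation p = 0.754 and 0.493). The AtPIF4 direction turned above the mean at 2000 bp, with 500 bp inside and with the gene body. Those with an AtPIF4 event were GAI, a DELLA repressor gene, and BZR1, a brassinosteroid response factor gene. In the heat and cold list, 3 of 21 genes had an AtPIF4 event against 2.58 and 5 an AtHY5 event against 5.83 (adjusted permutation p = 0.613 and 0.803). Neither direction was stable. For AtPIF4 it turned below the mean at 500 bp, at 2000 bp, with 500 bp inside and with the gene body, and for AtHY5 above it above the median score and with equal numbers of events. DREB2A, a drought and heat regulator gene, had the highest AtHY5 score among all fixed lists at 876. In the housekeeping list, 3 of 14 genes had an event of each protein, against 1.60 for AtPIF4 and 3.57 for AtHY5 (adjusted permutation p = 0.353 and 0.803). The AtHY5 direction turned above the mean in 5 of 7 alternatives. The genes with events were ACT2, UBC21 and UBC9. The AtPIF4 score of 1508, the highest among all fixed lists, came from an event 943 bp beyond an end of the actin gene ACT2.

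**Figure D4:**
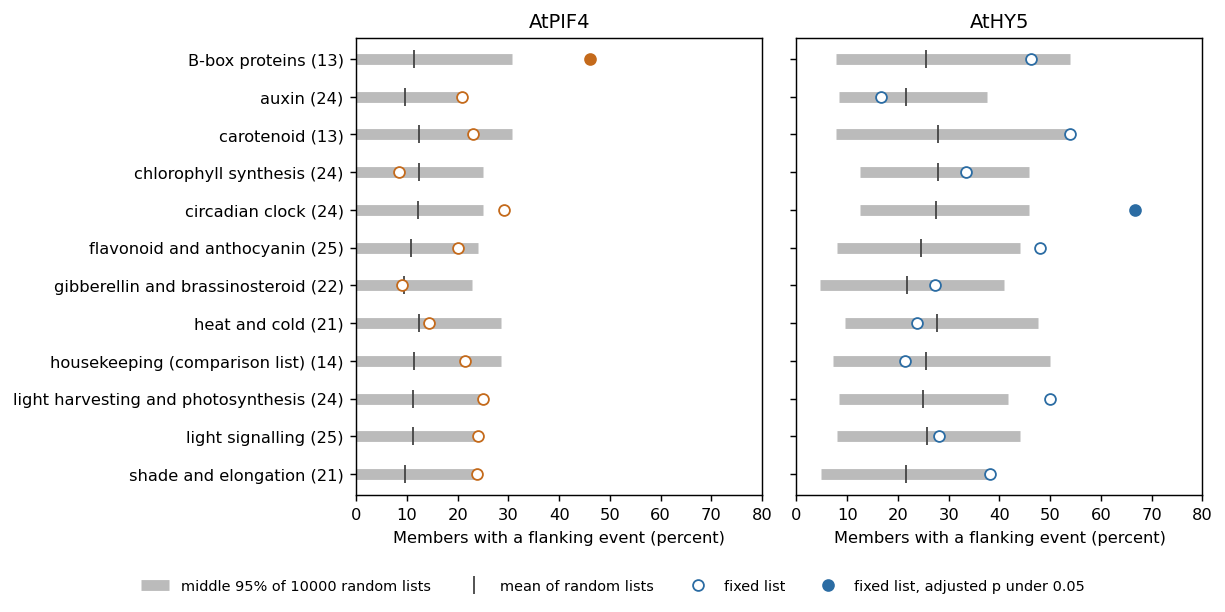
Percent of each fixed list's members, with list size in parentheses, that have a flanking AtPIF4 or AtHY5 event within 1000 bp. Points are the lists, ticks and grey bars are the mean and middle 95% of 10000 random lists, and the filled points are the B-box list for AtPIF4 and the circadian clock list for AtHY5, calls that both end at 2000 bp and in windows that reach into genes, and for the B-box list also at 500 bp.

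The highest scores of all lay at ribosomal RNA blocks. Of the 10 highest-scoring events, 8 for AtPIF4 and 10 for AtHY5 lay within 10 kb of one of the 4 nuclear rRNA genes of the gene table. AtPIF4 had 8 events there with 14.9% of its summed score, and AtHY5 had 28 with 24.7%. The genes with the highest flanking scores, AT2G01021 and AT2G01023 for AtPIF4 and AT3G41762 and AT2G01008 for AtHY5, owe them to these blocks. Outside them, the leading AtPIF4 genes were AT4G24090 with 2630, SHOT1 with 2503 and AT1G12150 with 2200. A single event of score 2086 then served the neighbours AT4G35840 and AT4G35850. AT5G02580 with 1977 followed, and then PAP5 and AT1G52950, which share an event of score 1771. The leading AtHY5 genes were AT2G21430 with 4828, RRA2, an arabinosyltransferase gene, with 3051, AT5G40315 with 2968, AT5G37440 with 2652, AT1G04030 with 2566 and AT5G58640 with 2467.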

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

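The MpHY5 list holds 219 events on unplaced scaffolds, sequences outside the named chromosomes that no comparison above used. These events were flagged because they had not been analysed and numbered more than a set floor of 3. They lay on 122 scaffolds and made up 0.683% of the list (Wilson interval 0.599 to 0.779). They held 54 of the 100 highest scores, and their median score was 217 against 84.4 for all events on named chromosomes. The V chromosome had a median score of 126. What these scaffolds carry was not analysed here, and no explanation was tested.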

How the results depend on the processing

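The gene body window, the equal number of AtHY5 events and the lists without repeated blocks were chosen after seeing the data, and the other alternatives were planned. In all, 211 alternative values were computed. The nearness of AtPIF4 and AtHY5 events stayed above the highest placement at both distances, above the median score, among the 1000 highest scores (20.5% and 21.5%), with class-keeping placements and without repeated blocks (46.4% and 19.0%). The number of genes with flanking events of both proteins, 1935, was 932 at 500 bp, 4198 at 2000 bp, 3298 with 500 bp inside, 856 above the median score, 4665 with the gene body, 1216 with equal numbers of events and 251 among genes with 1000 bp to both neighbours. More or fewer events or genes enter by construction, and the odds ratio stayed above 1 in each. The flank share, below the placed mean in the 1000 bp window, turned to above it for AtPIF4 at 500 bp (13.5% against 13.3%, within the range of placements), and the cause was not tested. It also turned with 500 bp inside, at 48.7% for AtPIF4 and 51.4% for AtHY5, a window that takes in gene sequence. For AtHY5 it fell below all placements at 2000 bp (26.0%).

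List calls were less stable. With 500 bp inside and with the gene body, which also added matching on gene length, 0 lists passed for AtPIF4 and 0 for AtHY5. At 500 bp, 0 passed for AtPIF4. Above the median score, 2 passed for AtPIF4, B-box and auxin (5 genes). The clock list for AtHY5 did not pass at 2000 bp (17 genes), with 500 bp inside (16) or with the gene body (18). Its adjusted permutation p ranged from 0.0024 to 0.186, and Fisher's exact test without matching gave an adjusted p of 0.000777. The B-box list for AtPIF4 did not pass at 500 bp (1 gene), at 2000 bp (7), with 500 bp inside (6) or with the gene body (6). Its adjusted permutation p ranged from 0.0276 to 0.823, and Fisher's exact test without matching gave an adjusted p of 0.022. The shade and elongation list passed at 2000 bp with 14 genes for AtPIF4 and 15 for AtHY5, but had 0 genes for AtPIF4 at 500 bp. The cause was not tested. The other 22 list results had 154 alternatives, of which 122 kept both direction and side of the threshold, 3 passed and 29 changed direction against the random mean without passing. Equal numbers of events left the AtPIF4 list unchanged, so its alternatives there could not change direction and count among those kept.

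For AtPIF4 these direction changes were, at 500 bp, heat and cold (1 gene) and shade and elongation (0); at 2000 bp, chlorophyll synthesis (7), flavonoid and anthocyanin (5), gibberellin and brassinosteroid (6) and heat and cold (4). With 500 bp inside they were gibberellin and brassinosteroid (4) and heat and cold (3). Above the median score they were chlorophyll synthesis (2) and light harvesting and photosynthesis (1). With the gene body they were chlorophyll synthesis (6), gibberellin and brassinosteroid (9) and heat and cold (3). For AtHY5 they were, at 500 bp, housekeeping (3) and light signalling (3); at 2000 bp, auxin (10), chlorophyll synthesis (10) and housekeeping (7). With 500 bp inside it was light signalling (9). Above the median score they were auxin (3), carotenoid (2, at the random mean), heat and cold (4) and housekeeping (2). With the gene body they were chlorophyll synthesis (12), housekeeping (8) and light signalling (12), and with equal numbers of events auxin (3), heat and cold (3) and housekeeping (2). The cause was not tested. Motif and 6-mer alternatives were not run, because no genome sequence was used here. With 1 library each, no library was left out. No paired analysis was possible because each protein has 1 library. Unknown depth limits what a missing event shows.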

Other observations

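The gene families, both family windows, the alternative without repeated blocks, and the tests on centre distances of 1 or 2 bp, on the remaining pairs and on the highest scores were chosen for testing only after the event lists had been seen. Across 18 gene families taken by symbol, 36 tests ran in each of 2 windows. In the flank window none passed an adjusted p of 0.05, and the lowest, 0.106, belonged to expansins and UDP-glycosyltransferases for AtHY5. Of 24 expansin genes, which encode cell wall loosening proteins, 12 had a flanking AtHY5 event against 5.78 in random lists. In the other window, which adds the gene body and matching on gene length, 15 had one against 11.7 (adjusted permutation p = 0.361). With the gene body and 1000 bp, 3 tests passed, each with an adjusted p of 0.0012. Of 64 UDP-glycosyltransferase genes, which encode enzymes that attach sugars to small molecules, 32 had an AtPIF4 event against 15.0 in random lists, and 47 had an AtHY5 event against 31.6. Of 100 NAC transcription factor genes, 68 had an AtHY5 event against 48.9. Members of such families can be neighbours and similar in sequence, so they are not independent, and the calls rest on 1 of the 2 windows. Window and matching changed together.

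AtPIF4 and AtHY5 events lie near each other far more often than placed events. Repeated sequence read in both libraries was one candidate explanation, but without repeated blocks 46.4% of AtPIF4 events still had an AtHY5 event within 100 bp. That step left out only 429 AtPIF4 and 869 AtHY5 events, near rRNA genes or the highest scores. Other repeated sequence was not identified, so it remains open. A shared preference for a class of DNA around genes was another, yet the highest of the class-keeping placements gave 3.72%. Those placements kept only whether an event lay inside a gene, within 1000 bp or farther, and were uniform within each class. A shared preference for finer parts of genes or for dense regions therefore remains open. Broad local background would spread the centre distances, whereas 54.2% of pairs within 100 bp lay within 20 bp, but most of these were 1 or 2 bp apart. Of the 2073 other pairs, 26.0% lay within 20 bp (24.1 to 27.9), against 18.8% for an even spread. Pairs per bp and side fell from 15.6 at 10 to 20 bp to 6.95 at 90 to 100 bp. An even spread does not describe these pairs, but broad background of another shape was not tested and remains open for them. A background common to both libraries at exact positions remains open, because inputs were not analysed here, and recognition of the same sequence by both proteins was not tested, because no genome sequence was used.

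Centres 1 or 2 bp apart belong to the same pattern. Calling noise around 1 common position would leave at least as many pairs at the same centre as at any other distance to 1 side. There were 11 pairs at the same centre, against 437 with AtHY5 1 bp higher and 408 with it 1 bp lower. A fixed offset between the lists would put AtHY5 on the same side, and it was on the higher-coordinate side in 50.7% of pairs (48.0 to 53.4). Both predictions were written after the centre distances had been seen. They describe these counts and are not independent tests. A candidate explanation that stays open is that the caller anchors events to a sequence motif at a point that differs between proteins by 1 or 2 bp in either orientation.

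More flanking events than in random lists passed the adjusted threshold in 2 tests of fixed gene lists. If low-scoring events were the cause, no list would pass above the median score, but the lowest adjusted p there was 0.0072, for the circadian clock and AtHY5. The prediction was written before the result, set aside while list counts were being explored, and restored in the same words once the result was known. It does not remove the dependence on the window, where adjusted permutation p for this list ranged up to 0.186. That highest value came from the gene body window, which also matched on gene length.

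The highest scores lie in a few repeated blocks. At least 8 of the 10 highest-scoring events of each protein lay within 10 kb of an rRNA gene or of such an event of the other protein. This restates what was seen and lends no support to the explanation that many genomic copies of a repeat read on 1 reference copy may raise scores there. Copy number and binding within the repeats were not tested, and both remain open.

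Of 2 hypotheses on the events 1 or 2 bp apart, the first was that they are the stronger events of both lists. Their median score percentile was 67.7 in the AtPIF4 list, against 46.5 for the other events. In the AtHY5 list it was 64.5 against 48.8. Both were higher, as that hypothesis predicted. The other events include those with no event of the other protein within 100 bp. Between the lowest and highest of 5 score classes, the share with such an event rose from 35.7% to 64.6% for AtPIF4. For AtHY5 it rose from 10.3% to 39.6%. Scores were not compared with those of near events at other distances. The higher percentiles are therefore not shown to be particular to 1 or 2 bp. The second hypothesis was that events 1 or 2 bp apart lie outside genes more often, and this was not borne out. The shares outside genes were 36.2% against 37.1% for AtPIF4 (Fisher's exact test, two-sided, p = 0.541) and 36.3% against 34.5% for AtHY5 (p = 0.211).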
